A study of Saccharomyces cerevisiae W303 with 86 samples.

How the data were processed

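Poly(A) RNA of 78 libraries and ribosome footprints of 8 libraries of Saccharomyces cerevisiae W303-1A were compared, in 29 groups and 7 sets named here after what each set changed (OXPHOS, PUF3, footprint, Puf3-15A, SNF1, MIG1 and INH1). Per the labels the replicates are biological, 3 per group for mRNA (6 for wild type of the OXPHOS set) and 2 for footprints. The labels give ethidium bromide at 25 µg/ml for 48 h, CuSO4 at 10 mM for 12 h, and cycloheximide at 100 µg/ml for 2 min before footprinting. The deposited values are RPKM, read numbers scaled by the authors to gene length and library total, for 7126 genes and other features in each library. The submitters' processing notes name CASAVA 1.9, STAR 2.6.1a, featureCounts, edgeR 3.28.1 and genome build R64, and the filters, gene lengths and treatment of reads that map to several places are not given in the sources used here. Outside the MIG1 set, the values multiplied by the annotated gene length were whole multiples of 1 step per library (within 0.05) for at least 95.2% of genes. For other genes a length that gave whole multiples was sought, so that approximate read numbers could be recovered for depth and for 1 alternative test. The MIG1 set appeared to count reads of repeated genes differently, and it was tested only within itself. Near-identical genes such as HXT6 and HXT7 have uncertain values in all sets. Of the identifiers, 6048 matched a locus tag of the reference annotation, and the others were kept under their own names.

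The comparisons, gene lists and the settings called planned below were set before the data were examined. That plan assumed read counts and a count model, and since the deposited values are RPKM, limma on the log scale took its place. Within each set, libraries were rescaled by trimmed means of log ratios (30% trimmed on the ratio, 5% on the level, unweighted), genes with at least 1 RPKM in as many libraries as the smallest group (3 for mRNA, 2 for footprints) were kept, and values were taken as log2(RPKM + 1). Fold changes are on that scale after rescaling, which understates changes of genes with low values, whereas printed RPKM levels are as deposited. A model with 1 mean per group was fitted over all libraries of a set with limma 3.58.1 in R 4.3.3 (moderated test with a trend of the variance, Benjamini-Hochberg threshold 0.05), for 30 comparisons of which 4 are interactions and 3 are of translational efficiency. Efficiency was the difference between the footprint change and the mRNA change in 1 model over the footprint libraries and the PUF3 set libraries of the 4 shared genotypes, rescaled within each assay, where the plan said over all libraries, so that a shift of translation as a whole cannot be seen. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

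The 28 gene lists were tested with limma's camera, a test against all other genes, at a preset correlation of 0.01 and again with the correlation estimated from the data. They held mitochondrially encoded proteins, complex III, complex IV, ATP synthase, complex II and the TCA cycle, retrograde targets, mitochondrial ribosome and translation, import and folding, assembly and heme, adenine nucleotide carriers and ATPase inhibitors, iron regulon, glucose-repressed sugar genes, gluconeogenesis with glyoxylate and acetate use, Adr1-dependent genes, hexose transporters, glycolysis, cytosolic ribosomal proteins, ribosome biogenesis, stress response, drug resistance, Gcn4 amino acid synthesis, hypoxic genes, phosphate regulon, copper-responsive, zinc-responsive, mating type a and haploid, mating type alpha, and sporulation and diploid genes. The changed gene was left out of the lists of its comparison.

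Named genes follow a fixed rule. It takes the changed genes, the 8 genes with the largest rise and the 8 with the largest fall of each main comparison (3 and 3 elsewhere) that were called, averaged at least 3 on the log2 scale, did not overlap between groups and had a symbol, up to 4 members of each list with the smallest p and members that went against their list, and genes chosen in advance such as CIT2 and PDR5. Not every gene the rule takes is printed.

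Other settings that were planned and run are median-ratio size factors, no filter, only the compared groups in the fit, the replicate number as a block, each replicate left out, mitochondrially encoded genes left out, wild-type libraries 1 to 3 or 4 to 6 alone, and the estimated correlation. Added later, after seeing the data, were no rescaling, a filter at 5 RPKM, pseudocounts of 0.1 and 5, voom on recovered reads, a separate spread for each assay, and mating-type and haploid genes left out. Replicate numbers were checked for pairing by correlating residuals of libraries with the same number. Tested on simulated data of the same spread, with 200 changed genes, the test recovered 96% of 2-fold and 92% of 1.5-fold changes for rho0 in the OXPHOS set, and 75% and 32% for rho0 footprints, which have fewer reads and only 2 libraries per group.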

Results

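The series measured mRNA, and in 1 set ribosome footprints, in the budding yeast strain W303-1A and its mutants, all of them grown to mid-log phase (optical density 0.5 to 0.8) in synthetic medium with 2% glucose, where yeast ferments and can live without respiration. The mutants lack a subunit of the respiratory chain or of the ATP synthase, or lack the mitochondrial genome altogether (rho0, made by growth in ethidium bromide), and some of them carry a further change in PUF3, SNF1, MIG1 or INH1. The 86 libraries fall into 29 groups and 7 sets. Groups of the 78 mRNA libraries had 3 biological replicates, except the first set's wild type with 6, and the 4 footprint groups had 2. The reads recovered per library from the deposited values numbered 9973743 to 13997745 in the OXPHOS set, 9382218 to 14328403 in the PUF3 set and 8630852 to 10010457 in the Puf3-15A set. They numbered 9081325 to 12072360 in the SNF1 set, 18807917 to 71113298 in the MIG1 set, 9269585 to 14411558 in the INH1 set and 1151177 to 2987726 in the shallower footprint libraries.

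The deleted genes were at or below 1.77 RPKM in every library labelled as lacking them, while the puf3-15A allele cannot be checked from RPKM. In the OXPHOS set, COR1 (YBL045C, chromosome II, 134143 to 135516), which encodes a core subunit of complex III, was at 0.377 ± 0.164 RPKM in the cor1 deletion (SD, n = 3) against 293 ± 42.0 RPKM in wild type (n = 6). COX9 (YDL067C, chromosome IV, 334217 to 334396), which encodes a subunit of complex IV, was at 0.441 ± 0.404 against 440.3 ± 66.0 RPKM. ATP7 (YKL016C, chromosome XI, 407465 to 407989), a subunit of the ATP synthase stalk, was at 0.822 ± 0.836 against 316 ± 48.8 RPKM. The mitochondrially encoded COX1 and OLI1 were listed at 0 in the 3 rho0 libraries of this set, and at 3.90 ± 0.448 and 5.76 ± 1.37 RPKM in its wild type. Footprints check rho0 poorly, with COX1 at 1.87 RPKM in wild type and 0.170 in rho0, and OLI1 at 0 in both.

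The first set asked how loss of complex III, complex IV, the ATP synthase or mitochondrial DNA changes the mRNA of cells that can grow without respiration. Against pooled wild-type libraries that differ, loss of COR1 lowered nuclear genes of the respiratory machinery. Of the 14 ATP synthase subunit genes, 13 fell and 14 fell adjusted over the list alone, with a median of -0.51 on the log2 scale (limma's camera test, adjusted p = 4.6e-27). ATP5, for example, fell by 0.57 (SE 0.05). INH1, the inhibitor of the ATP synthase's reverse reaction, fell from 234 ± 42.5 to 129 ± 2.46 RPKM (adjusted p = 5.8e-05), ATP19 fell by 0.70 (SE 0.07) and the ADP/ATP carrier PET9 fell by 0.43 (SE 0.04, adjusted p = 1.2e-06). Glycolysis went the other way, with 12 of 16 genes higher, 13 adjusted over the list alone, and none lower (adjusted p = 1.5e-15), among them TDH2 at 0.60 (SE 0.06) and FBA1 at 0.23 (SE 0.03).

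In the same comparison, 3 of 8 complex III genes fell, 6 adjusted over the list alone, with QCR2 at -0.45 (SE 0.07), although this list's adjusted p of 9.5e-06 became adjusted p = 0.33 with an estimated correlation. Complex IV had 5 of 10 genes lower, 7 adjusted over the list alone, led by COX4 at -0.40 (SE 0.07), while COX26 went against them at 1.38 (SE 0.31), and the list's adjusted p of 0.0010 became adjusted p = 0.38 with an estimated correlation. DLD3, a target of the retrograde pathway that signals mitochondrial damage to the nucleus, rose by 0.30 (SE 0.04), while the classical reporter CIT2 was at -0.10 (SE 0.15, adjusted p = 0.73). Beyond these groups the cor1 deletion raised the heme oxygenase HMX1 from 39.3 ± 1.42 to 85.8 ± 3.97 RPKM. It lowered the glycerophosphoinositol transporter GIT1 by 1.66 (SE 0.17), the polyamine exporter TPO2 by 1.65 (SE 0.35), the stress gene HSP12 by 1.15 (SE 0.17) and the cell wall gene HPF1 by 1.10 (SE 0.14). In all, limma called 420 of 6757 genes, 237 higher and 183 lower. The count was 132 with only the groups compared in the fit, 2840 against wild-type libraries 4 to 6 alone, and 259 and 278 without cor1 libraries 2 and 3.

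In the cox9 deletion, all 14 ATP synthase genes fell (median -0.61, adjusted p = 2.8e-28), with ATP19 at -0.80 (SE 0.07), INH1 at -0.97 (SE 0.10) and PET9 at -0.47 (SE 0.04). All 9 complex III genes fell, led by QCR2 at -0.66 (SE 0.07) and COR1 at -0.60 (SE 0.08) (adjusted p = 6.1e-12, and adjusted p = 0.073 with an estimated correlation). Of the 9 other complex IV genes, 6 fell, and 7 fell and 2 rose adjusted over the list alone, with COX5A at -0.48 (SE 0.06) (adjusted p = 1.2e-05, and adjusted p = 0.22 with an estimated correlation). Glycolytic genes rose in 13 of 16 cases, 15 adjusted over the list alone, with TDH2 at 0.64 (SE 0.06) and ADH1 at 0.34 (SE 0.04) (adjusted p = 1.5e-18). Of the 25 iron regulon genes 5 rose, among them HMX1 at 0.61 (SE 0.06) and FIT2 at 0.62 (SE 0.14), while FET5 fell by 0.19 (SE 0.05) (adjusted p = 0.0023, and 0.039 with an estimated correlation). TPO2, HPF1 and GIT1 fell again, by 1.95 (SE 0.35), 1.18 (SE 0.14) and 1.02 (SE 0.17). The called genes numbered 448, 240 higher and 208 lower. This count was 235 with only the groups compared, 2871 against wild-type libraries 4 to 6 alone, and 251, 268 and 217 without cox9 libraries 1, 2 and 3.

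Loss of ATP7 changed many more genes, 3058 of 6757, with 1408 higher and 1650 lower. The drug efflux pump gene PDR5 rose from 93.2 ± 4.41 to 485 ± 53.8 RPKM (log2 change 2.27, SE 0.06, adjusted p = 6.3e-14). Of the pleiotropic drug resistance genes 8 of 11 rose, including the activator PDR3 at 0.77 (SE 0.05) and PDR15 at 1.73 (SE 0.13) (adjusted p = 2.1e-05). Genes for the mitochondrial ribosome and its translation factors rose in 74 of 76 cases, with a median of 0.53 (adjusted p = 3.2e-39). MRPL31 rose by 0.85 (SE 0.04) and MEF1 by 0.76 (SE 0.05), and MEF2 alone fell, by 0.65 (SE 0.12). Cytosolic ribosomal protein genes moved the opposite way, with 133 of 137 lower and a median of -0.38 (adjusted p = 8.0e-47, and adjusted p = 0.094 with an estimated correlation), RPL6B at -0.44 (SE 0.03) among them.

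The 13 other ATP synthase genes all fell in the atp7 deletion (median -0.54, adjusted p = 2.5e-10, and adjusted p = 0.085 with an estimated correlation), and INH1 fell by 1.24 (SE 0.10). The assembly factors of the respiratory chain rose in 23 of 30 cases, 24 adjusted over the list alone, among them CBP4 at 0.96 (SE 0.07) (adjusted p = 4.6e-10, and adjusted p = 0.10 with an estimated correlation). HEM1 and COX19 fell instead, by 0.45 (SE 0.06) and 0.57 (SE 0.15). In the group for protein import and folding in mitochondria, 22 of 32 rose, such as HSP60 at 0.55 (SE 0.05) (adjusted p = 3.5e-07, and adjusted p = 0.085 with an estimated correlation). TIM21 and TIM44 fell by 0.15 (SE 0.05) and 0.11 (SE 0.04). The iron regulon rose in 11 of 25 genes, with HMX1 at 1.36 (SE 0.06) and the siderophore transporter SIT1 at 1.21 (SE 0.07) (adjusted p = 1.5e-05). Retrograde targets rose in 6 of 8 cases, 7 adjusted over the list alone, with IDH1 at 0.91 (SE 0.07), ACO1 at 0.70 (SE 0.12) and CIT2 at 0.46 (SE 0.15) (adjusted p = 0.00032, and adjusted p = 0.13 with an estimated correlation).

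Stress genes rose in 23 of 30 cases in the atp7 deletion, 26 adjusted over the list alone, with HSP12 at 1.84 (SE 0.17), DDR2 at 1.76 (SE 0.24) and RTC3 at 1.75 (SE 0.28) (adjusted p = 3.6e-08, and adjusted p = 0.28 with an estimated correlation). The 53 ribosome biogenesis genes all fell, with a median of -0.55, and NOP1 fell by 0.56 (SE 0.10) (adjusted p = 1.0e-11, and adjusted p = 0.37 with an estimated correlation). These 2 groups differ between the wild-type libraries themselves: libraries 4 to 6 had all 53 ribosome biogenesis genes higher and 25 of 30 stress genes lower than libraries 1 to 3. Against libraries 1 to 3 alone, 45 ribosome biogenesis genes were lower (median -0.24) and 19 stress genes higher, and against libraries 4 to 6, 53 were lower (median -0.86) and 27 higher. In all, 14 of the 28 lists differed between these 2 trios. In libraries 4 to 6, 15 of 15 TCA cycle genes, 8 of 9 of complex III, 7 of 10 of complex IV, 9 of 14 of the ATP synthase, 6 of 8 retrograde targets, 18 of 30 assembly genes and 21 of 76 mitochondrial ribosome genes were lower, and 47 of 137 ribosomal protein genes higher. ATP synthase medians ran from -0.80 to -0.42 over both trios and the 4 mutants. Complex III in the cor1 deletion went from -0.47 (8 lower) against libraries 1 to 3 to -0.097 (2 lower) against 4 to 6, and the TCA cycle in the atp7 deletion from -0.20 to 0.17. With the RPKM as deposited and no rescaling of libraries, the atp7 comparison split into 2109 higher and 1044 lower.

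In the rho0 strain the genes of the mitochondrial ribosome rose in 75 of 76 cases, with a median of 0.91 (adjusted p = 1.9e-41, and 0.021 with an estimated correlation). MRPL31 rose by 1.40 (SE 0.04) and MEF1 by 1.17 (SE 0.05), and MEF2 fell by 1.20 (SE 0.12). The import and folding genes rose in 28 of 32 cases, with HSP60 at 0.95 (SE 0.05) and HSP10 at 0.93 (SE 0.05), and TIM21 fell by 0.23 (SE 0.05) (adjusted p = 5.5e-12). Of the assembly genes, 25 of 30 rose, among them the copper chaperone COX17 at 1.43 (SE 0.10) and CBP4 at 1.35 (SE 0.07), and HEM15 fell by 0.46 (SE 0.12) (adjusted p = 2.0e-10, and adjusted p = 0.075 with an estimated correlation). Retrograde targets rose in 7 of 8 cases, led by the isocitrate dehydrogenase gene IDH1 at 2.02 (SE 0.07) and the aconitase ACO1 at 1.57 (SE 0.12) (adjusted p = 4.2e-05, and adjusted p = 0.075 with an estimated correlation). CIT2 was at 0.29 (SE 0.15, adjusted p = 0.11). PDR5 reached 647 ± 30.8 RPKM, a log2 change of 2.72 (SE 0.06), and 9 of 11 drug resistance genes rose, 10 adjusted over the list alone (adjusted p = 3.5e-05).

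The structural genes of the respiratory machinery fell in rho0. The ATP synthase list had 13 of 14 lower (median -0.66, adjusted p = 3.9e-09, and adjusted p = 0.075 with an estimated correlation), with ATP2 at -1.08 (SE 0.05). All 9 complex III genes fell, QCR2 by 0.74 (SE 0.07) (adjusted p = 3.9e-05, and adjusted p = 0.20 with an estimated correlation). In complex IV, 8 of 10 fell, COX4 by 1.15 (SE 0.07), while the hypoxic isoform COX5B rose by 0.66 (SE 0.17) (adjusted p = 0.0020, and adjusted p = 0.26 with an estimated correlation). Cytosolic ribosomal protein genes fell in 131 of 137 cases (median -0.46, adjusted p = 1.9e-41, and adjusted p = 0.081 with an estimated correlation), against which RPS9A rose by 0.38 (SE 0.08) and RPL9B by 0.19 (SE 0.06). The phosphate regulon fell in 14 of 15 genes, with a median of -1.94 (adjusted p = 4.5e-16), where the atp7 deletion had 9 lower and 2 higher. The regulator SPL2 fell from 92.9 ± 4.84 to 11.2 ± 1.62 RPKM, the phosphate transporter PHO84 from 1022 ± 120 to 176 ± 13.7 RPKM and the acid phosphatase PHO5 by 2.43 (SE 0.09).

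Other genes that rose in rho0 were HSP12, from 168 ± 15.7 to 2221 ± 122 RPKM, and ZPS1 at 3.23 (SE 0.45). Of the genes for gluconeogenesis, the glyoxylate cycle and acetate use, 13 of 17 rose, with IDP2 at 1.74 (SE 0.10) (adjusted p = 7.4e-05). The iron regulon rose in 13 of 25 genes, with FIT2 at 1.71 (SE 0.14) (adjusted p = 0.00042). The sporulation and diploid genes rose in 6 of 7 cases, with REC8 at 0.95 (SE 0.14) (adjusted p = 0.011, and adjusted p = 0.056 with an estimated correlation). In total 3296 genes were called, 1698 higher and 1598 lower, and without rescaling the split was 2045 higher and 1128 lower.

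Across the 4 mutants of this set, 146 genes were called in the same direction, 78 higher and 68 lower, where independent lists of these sizes would share 0.766. A further 157 genes were called in opposite directions in at least 1 pair. The shared genes included 12 of the 14 ATP synthase genes, all lower, and 7 of 16 glycolytic genes, all higher. The 6 shared wild-type libraries, simulated as alike (they are not), gave unchanged groups a covariance of 0.0096 to 0.0098. The covariance of fold changes for atp7 and rho0 was 0.101, and 0.1004 and 0.0449 in 2 splits that gave each its own wild-type libraries. The other pairs had 0.0335 (cor1 and cox9), 0.0418 (cor1 and atp7), 0.0495 (cox9 and atp7), 0.0183 (cor1 and rho0) and 0.0244 (cox9 and rho0). Their splits gave -0.0193 to 0.0401. All lay below the pooled values, which unlike shared controls may raise. Over all pairs and splits, 208 to 2034 calls shared direction.

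PUF3 (YLL013C, chromosome XII, 122075 to 124714) encodes an RNA-binding protein that binds mRNAs of nuclear-encoded mitochondrial proteins, many of them for the mitochondrial ribosome. The PUF3 set deleted it in wild type, in the atp7 deletion and in rho0, to ask whether Puf3 acts differently on its targets when the ATP synthase or mitochondrial DNA is missing. PUF3 mRNA was at or below 0.194 RPKM in all 9 libraries of the deletions, against 42.9 ± 1.13 RPKM in wild type, 60.2 ± 4.88 in the atp7 deletion and 66.7 ± 6.99 in rho0 (SD, n = 3 each). ATP7 was listed at 0 in all 6 libraries of the atp7 deletions.

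In wild type, deleting PUF3 raised part of the mitochondrial translation machinery. Of 76 genes, 33 rose and 3 fell, and 43 rose and 4 fell adjusted over the list alone, with a median of 0.17 (limma's camera test, adjusted p = 7.5e-10, and adjusted p = 0.15 with an estimated correlation). MRPL37 rose by 0.58 (SE 0.07), IMG1 by 0.57 (SE 0.07) and the elongation factor TUF1 by 0.34 (SE 0.04), while MRP20 fell by 0.33 (SE 0.09), MRPL15 by 0.17 (SE 0.05) and RSM28 by 0.17 (SE 0.05). The Puf3 target COX17 rose from 169 ± 9.49 to 268 ± 18.9 RPKM (adjusted p = 9.1e-06). Of 32 import and folding genes 21 rose, 25 adjusted over the list alone, among them TIM10 at 0.61 (SE 0.06) and HSP10 at 0.63 (SE 0.08), with MDJ1 lower by 0.52 (SE 0.14) (adjusted p = 7.0e-12). The citrate synthases CIT2 and CIT1 fell by 1.27 (SE 0.26) and 0.84 (SE 0.16). Among genes of complex II and the TCA cycle 5 of 15 fell (adjusted p = 7.3e-05, and adjusted p = 0.27 with an estimated correlation). Of 30 stress genes 10 fell, such as CTT1 at -1.27 (SE 0.29) (adjusted p = 9.0e-09, and adjusted p = 0.32 with an estimated correlation). HSP12 fell by 1.53 (SE 0.40).

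The genes that rose most in this comparison were those of mating type a cells, MFA1 from 138 ± 35.7 to 589 ± 32.4 RPKM, FUS3 by 2.11 (SE 0.13) and STE2 from 100.2 ± 21.5 to 391 ± 6.88 RPKM. All 7 genes of this list rose (adjusted p = 5.8e-15). In this set, wild type was the group with low values of these genes: MFA1 was at 496 to 773 RPKM on average in the other 5 groups. The comparison called 1066 of 6812 genes, 601 higher and 465 lower, and the count moved with single libraries, to 2402 without wild-type library 1, 404 and 406 without wild-type libraries 2 and 3, and 418 and 613 without puf3 libraries 2 and 3. With only the groups compared in the fit it was 174.

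In the atp7 deletion, the loss of PUF3 lowered the mitochondrial ribosome instead. Of 76 genes, 53 fell and none rose, 63 fell and 2 rose adjusted over the list alone, with a median of -0.37 (adjusted p = 3.1e-97, and 3.3e-05 with an estimated correlation). MRPL3 fell by 0.73 (SE 0.05), RSM25 by 0.62 (SE 0.04), MRPL17 by 0.68 (SE 0.05) and MRP13 by 0.69 (SE 0.05), so that this list held 53 of the 152 genes called. Assembly factors fell in 10 of 30 cases, 13 adjusted over the list alone, with COX10 at -0.81 (SE 0.07) and BCS1 at -0.50 (SE 0.05), while COX17 rose by 0.33 (SE 0.07) (adjusted p = 3.2e-11, and adjusted p = 0.097 with an estimated correlation). Only 12 genes rose, among them the zinc-responsive ADH4, from 51.2 ± 7.57 to 173 ± 16.9 RPKM, ZPS1 at 2.05 (SE 0.46) and ZAP1 at 0.51 (SE 0.11). The total of 152 became 549 with only the groups compared in the fit.

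In rho0 the same deletion changed 2077 genes, 1018 higher and 1059 lower. The mitochondrial ribosome genes fell in 69 of 76 cases, 71 adjusted over the list alone, with a median of -0.57 (adjusted p = 2.9e-46, and 0.0015 with an estimated correlation). NAM9 fell by 0.91 (SE 0.04), MRPL17 by 1.08 (SE 0.05), MRPL3 by 0.98 (SE 0.05) and RML2 from 138 ± 3.93 to 62.2 ± 2.58 RPKM, and MEF2 alone rose, by 0.35 (SE 0.12). Assembly factors fell in 18 of 30 cases, COX10 by 0.96 (SE 0.07) and BCS1 by 0.74 (SE 0.05), against which COX16 and COX20 rose by 0.29 (SE 0.08) and 0.31 (SE 0.09) (adjusted p = 8.8e-07, and adjusted p = 0.18 with an estimated correlation). The import genes fell in 17 of 32 cases, TIM9 by 0.68 (SE 0.07) and TOM70 by 0.39 (SE 0.04), with HSP10 higher by 0.36 (SE 0.08) (adjusted p = 0.00012, and adjusted p = 0.17 with an estimated correlation). Ribosomal protein genes fell too, 90 of 137 (median -0.30, adjusted p = 2.0e-17, and adjusted p = 0.42 with an estimated correlation), and 36 of 53 ribosome biogenesis genes (median -0.50, adjusted p = 2.6e-13, and adjusted p = 0.42 with an estimated correlation). The hexose transporters HXT4 and HXT2 fell by 1.96 (SE 0.45) and 1.35 (SE 0.42).

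Of complex II and the TCA cycle, 14 of 15 rose, 15 adjusted over the list alone, with ACO1 at 1.01 (SE 0.07), IDH1 at 0.88 (SE 0.09) and FUM1 at 0.40 (SE 0.04) (adjusted p = 6.3e-11, and adjusted p = 0.067 with an estimated correlation). Retrograde targets rose in 7 of 8 cases, with CIT2 from 239 ± 29.2 to 505 ± 20.7 RPKM, CIT1 at 1.07 (SE 0.16), DLD3 at 1.02 (SE 0.10) and the pyruvate carboxylase PYC1 at 2.18 (SE 0.28) (adjusted p = 4.1e-06, and adjusted p = 0.060 with an estimated correlation). PDR5 rose from 881 ± 8.46 to 2043 ± 42.3 RPKM, PDR15 by 2.02 (SE 0.11) and SNQ2 by 0.79 (SE 0.05), among 10 of 11 drug resistance genes (adjusted p = 2.8e-10). The carbonic anhydrase NCE103 rose from 198 ± 136 to 1802 ± 205 RPKM. Of the stress genes 16 of 30 rose, DDR2 by 1.91 (SE 0.19), while HSP30 fell by 2.78 (SE 0.91) (adjusted p = 2.6e-07, and adjusted p = 0.38 with an estimated correlation). Hypoxic genes fell in 5 of 15 cases, ERG11 by 0.44 (SE 0.07) and OLE1 by 0.94 (SE 0.21) (adjusted p = 0.027, and adjusted p = 0.42 with an estimated correlation). In rho0 of this set, with HSP12 at 1336 ± 1194 RPKM, library 1 stood apart, with a chi-square per degree of freedom on recovered reads of 54.3 and 54.4 against libraries 2 and 3, and 2.18 between these. Library 1 stood apart likewise in wild type (35.7 and 34.6, against 2.32), the puf3 deletion (13.1 and 14.7, against 3.48) and rho0 without PUF3 (10.8 and 11.1, against 2.62). The count was 1361 with only the groups compared in the fit.

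Tested as an interaction with the background, 68 of the 76 mitochondrial ribosome genes had a lower effect of the PUF3 deletion in the atp7 deletion than in wild type (median -0.52, adjusted p = 2.3e-55). In rho0, 74 had a lower one (median -0.76, adjusted p = 2.5e-40), with MEF2 the other way at 0.56 (SE 0.17). For rho0 the effect also differed for PDR5 by 1.17 (SE 0.06), CIT2 by 2.30 (SE 0.37) and COX17 by -0.58 (SE 0.10). It differed for 53 of 53 ribosome biogenesis genes (median -0.92, adjusted p = 5.0e-17, and adjusted p = 0.30 with an estimated correlation) and for 22 of 30 stress genes (median 1.31, adjusted p = 4.6e-10, and adjusted p = 0.20 with an estimated correlation). In all, 507 genes differed in the atp7 deletion, a count that was 1787 without wild-type library 1, and 2514 differed in rho0, 1167 higher and 1347 lower, or 1408 higher and 1049 lower without rescaling. All 7 mating type a genes differed in both, with medians of -1.86 and -2.10, wild type being the group where they were low.

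The set also repeated the comparison of the atp7 deletion and of rho0 with wild type. In the atp7 deletion 3717 genes were called, 1997 higher and 1720 lower (2324 and 1292 without rescaling), including 74 of 76 mitochondrial ribosome genes higher and MEF2 lower by 0.77 (SE 0.12), 53 of 53 ribosome biogenesis genes lower and 27 of 30 stress genes higher. In rho0, 2654 genes were called, 1443 higher and 1211 lower, with 73 of 76 mitochondrial ribosome genes higher (median 0.70), 13 of 14 ATP synthase genes lower (median -0.74), and 14 of 15 phosphate genes lower, with PHM8 higher by 0.64 (SE 0.18). PDR5 was at 2.02 (SE 0.04) and INH1 fell by 2.13 (SE 0.21). With only the groups compared in the fit, the rho0 count was 1270.

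The Puf3-15A set replaced PUF3 with puf3-15A, an allele that blocks the hyperphosphorylation of the protein, in wild type and in rho0. The mRNA of PUF3 itself was close in strains with and without the allele, at 26.7 ± 1.98 against 29.8 ± 1.37 RPKM in wild type (adjusted p = 0.23) and 45.6 ± 1.59 against 48.8 ± 1.35 RPKM in rho0 (adjusted p = 0.62; SD, n = 3 each). In wild type the allele lowered mitochondrial genes broadly and by small steps. The mitochondrial ribosome genes fell in 75 of 76 cases, 76 adjusted over the list alone, with a median of -0.45 (limma's camera test, adjusted p = 5.7e-69), among them RSM25 at -0.64 (SE 0.04) and MRPL3 at -0.55 (SE 0.03). All 14 ATP synthase genes fell (median -0.33, adjusted p = 2.8e-17), as did all 9 complex III genes (median -0.44, adjusted p = 5.9e-15), with ATP2 at -0.41 (SE 0.03) and COR1 at -0.50 (SE 0.04).

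Assembly factors fell in 21 of 30 cases in wild type, among them BCS1 at -0.61 (SE 0.04) (adjusted p = 2.0e-18). Import and folding genes fell in 21 of 32, with SSC1 at -0.38 (SE 0.03) (adjusted p = 1.2e-17). TCA cycle genes fell in 10 of 15, with CIT1 at -0.51 (SE 0.05) and SDH2 at -0.59 (SE 0.07) (adjusted p = 2.0e-11, and adjusted p = 0.11 with an estimated correlation). Of the adenine nucleotide carriers and ATPase inhibitors, 3 of 7 fell, PET9 by 0.42 (SE 0.03), INH1 by 0.70 (SE 0.07) and STF1 by 0.30 (SE 0.07) (adjusted p = 0.00046, and adjusted p = 0.070 with an estimated correlation). Ribosome biogenesis genes rose in 38 of 53 cases (median 0.23, adjusted p = 5.0e-20, and adjusted p = 0.25 with an estimated correlation) and HXT2 rose by 0.51 (SE 0.09). Of 6776 genes, 935 were called, 429 higher and 506 lower, of which only 2 rose and 4 fell at least 2-fold, and without rescaling the split was 212 and 629. The count was 535 without wild-type library 1, 577 and 525 without puf3-15A libraries 2 and 3, and 496 with only the groups compared in the fit.

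In rho0 the allele again lowered 75 of 76 mitochondrial ribosome genes, 76 adjusted over the list alone, with a median of -0.68 (adjusted p = 5.5e-70). MRPL31 fell by 0.85 (SE 0.03), MEF1 from 151 ± 3.96 to 76.6 ± 5.57 RPKM, the tRNA synthetase MSY1 by 0.98 (SE 0.05), MSC6 by 0.97 (SE 0.04) and MAM33 by 0.93 (SE 0.06). Assembly factors fell in 22 of 30 cases, PET117 by 1.08 (SE 0.11), COX17 from 358 ± 7.55 to 170.3 ± 13.7 RPKM and COX10 by 0.95 (SE 0.05), with HEM1 higher by 0.18 (SE 0.04) (adjusted p = 1.4e-15). Import and folding genes fell in 25 of 32, HSP60 by 0.54 (SE 0.03) (adjusted p = 5.0e-23).

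In rho0 with the allele, Gcn4 targets for amino acid synthesis rose in 27 of 31 cases, 28 adjusted over the list alone, with ARG1 at 0.88 (SE 0.03), and LYS4 fell by 0.12 (SE 0.04) (adjusted p = 2.6e-25). Retrograde targets rose in 7 of 8 cases, IDH1 by 0.77 (SE 0.03), ACO1 by 0.67 (SE 0.03), DLD3 by 0.60 (SE 0.03) and CIT2 by 0.45 (SE 0.07) (adjusted p = 1.6e-11). Drug resistance genes rose in 9 of 11, with PDR5 at 0.57 (SE 0.04), PDR15 at 0.82 (SE 0.05) and RSB1 at 0.95 (SE 0.07) (adjusted p = 2.0e-11). The phosphate regulon fell in 11 of 15 cases, SPL2 by 1.07 (SE 0.08), with PHO8 higher by 0.14 (SE 0.03) (adjusted p = 5.2e-08). Mating type a genes fell in 6 of 7 cases, MFA1 by 0.74 (SE 0.07) (adjusted p = 3.5e-05). In total 1220 genes were called, 627 higher and 593 lower, or 424 and 1012 without rescaling.

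The effect of the allele differed between rho0 and wild type for 1272 genes, 641 higher and 631 lower, tested as an interaction. The complex III genes differed in 9 of 9 cases (median 0.55, adjusted p = 8.0e-13), the ATP synthase genes in 12 of 14 (median 0.35, adjusted p = 8.3e-12) and the TCA cycle genes in 14 of 15 (median 0.52, adjusted p = 4.4e-17), each of them with a higher effect in rho0. There the allele left the ATP synthase list at a median of 0.03 and raised 3 of 9 complex III genes, 5 adjusted over the list alone (adjusted p = 0.0028, and adjusted p = 0.13 with an estimated correlation), and 10 of 15 TCA cycle genes (adjusted p = 2.9e-08, and adjusted p = 0.13 with an estimated correlation). For the mitochondrial ribosome the effect was lower in rho0 for 35 of 76 genes, with MEF2 the other way at 0.32 (SE 0.09) (median -0.21, adjusted p = 1.1e-13). Without rho0 library 1 the count was 770.

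The same set compared rho0 with wild type, with 3710 genes called, 1933 higher and 1777 lower. Of the mitochondrial ribosome genes 73 of 76 rose, with a median of 0.64, and MEF2 fell by 1.33 (SE 0.07), while 14 of 14 ATP synthase genes fell (median -0.66) and 130 of 137 cytosolic ribosomal protein genes fell. The 5 mitochondrially encoded genes that could be tested all fell to 0 (median -1.49, adjusted p = 0.0019, and adjusted p = 0.15 with an estimated correlation), OLI1 from 37.6 RPKM. PDR5 rose by 2.36 (SE 0.04), and INH1 fell to 82.8 ± 3.54 RPKM.

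**Figure D1:**
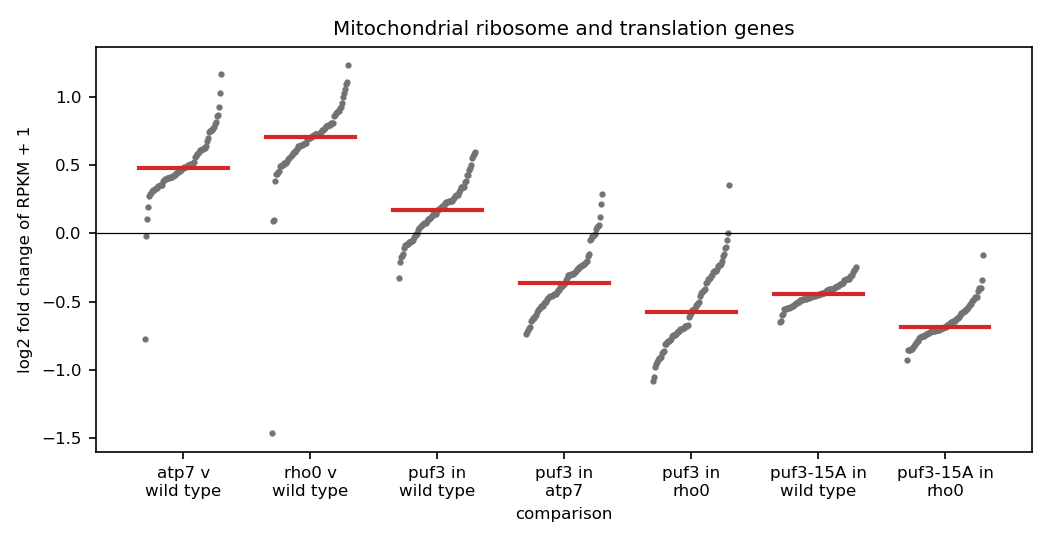
Change of the 76 genes of mitochondrial ribosome and translation in 7 comparisons of the PUF3 and Puf3-15A sets, with 1 point per gene at its log2 fold change (vertical axis, log2 of RPKM + 1) and the median as a red line. The medians are 0.48 and 0.70 for the atp7 deletion and rho0 against wild type, 0.17, -0.37 and -0.57 for the PUF3 deletion in wild type, the atp7 deletion and rho0, and -0.45 and -0.68 for puf3-15A in wild type and rho0.

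SNF1 (YDR477W, chromosome IV, 1412373 to 1414274) encodes the yeast AMP-activated kinase, which lifts glucose repression. The SNF1 set deleted it in untreated cells and in cells that had lost mitochondrial DNA through ethidium bromide, to ask which part of the response to that loss needs the kinase. SNF1 mRNA was at 0.0943 ± 0.0879 against 95.2 ± 3.21 RPKM in untreated cells and at 0.179 ± 0.220 against 142 ± 7.02 RPKM in treated cells (SD, n = 3 each). OLI1 was listed at 0 in all 6 treated libraries and averaged 32.3 ± 12.6 RPKM in untreated wild type. Cells without SNF1 also had genes of mating type a and of haploid cells at medians of 1.93% and 19.1% of wild type when untreated and 4.93% and 19.8% when treated. Whether these groups also differ in cell type or strain is open, and the changes below cannot be assigned to SNF1 alone.

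In untreated cells without SNF1, the high-affinity glucose transporter gene HXT2 was at 18.6 ± 6.63 against 211 ± 82.3 RPKM and the hexokinase gene HXK1 lower by 0.86 (SE 0.15). Phosphate genes fell in 14 of 15 cases, PHO84 by 4.27 (SE 0.20) and PHO5 by 3.25 (SE 0.20), with GIT1 higher by 0.61 (SE 0.19) (limma's camera test, adjusted p = 8.6e-12, and adjusted p = 0.18 with an estimated correlation). Glycolysis genes fell in 12 of 16 cases, FBA1 by 0.70 (SE 0.13), while TDH1 rose by 0.80 (SE 0.13) (adjusted p = 0.0014, and adjusted p = 0.75 with an estimated correlation). Stress genes rose in 12 of 30 cases, HSP26 by 2.62 (SE 0.41), with GSY1 lower by 0.85 (SE 0.11), PNC1 by 0.33 (SE 0.10) and XBP1 by 0.45 (SE 0.15) (adjusted p = 0.0038, and adjusted p = 0.75 with an estimated correlation). Genes of gluconeogenesis and acetate use rose in 6 of 17 cases, MDH2 by 1.35 (SE 0.16) (adjusted p = 0.00033, and adjusted p = 0.62 with an estimated correlation). The steepest falls were in mating type a genes, all 7 of them (median -5.35, adjusted p = 1.0e-11), with MFA1 at 1.85 ± 1.61 against 409.8 ± 21.9 RPKM. Of the 4 genes of mating type alpha, STE3 rose, by 0.56 (SE 0.19) to 2.85 RPKM, and the list's adjusted p was 0.69. In all, 1975 of 6776 genes were called, 880 higher and 1095 lower, or 1719 and 607 without rescaling, which shifted the median by 0.14.

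Ethidium bromide treatment of wild type gave the broadest response of this set, with 4880 genes called, 2372 higher and 2508 lower. Carbon source genes rose: HXT6 from 1.48 ± 0.431 to 207 ± 31.2 RPKM, HXT4 by 5.06 (SE 0.12), HXK1 from 102 ± 8.38 to 2695 ± 493 RPKM, SUC2 by 2.81 (SE 0.19) and RGI1 by 5.68 (SE 0.17). Of the glucose-repressed sugar genes 12 of 15 rose (median 2.37, adjusted p = 1.3e-05, and adjusted p = 0.24 with an estimated correlation). Hexose transporters rose in 6 of 7 cases, with HXT1 lower by 1.24 (SE 0.14) (adjusted p = 0.0032, and adjusted p = 0.24 with an estimated correlation). Gluconeogenesis and acetate genes rose in 16 of 17 cases, ALD4 by 3.94 (SE 0.14) (adjusted p = 7.2e-05, and adjusted p = 0.30 with an estimated correlation), while ADH2 stood at -0.42 (SE 0.19, adjusted p = 0.067). Stress and glycogen genes rose in 29 of 30 cases, GSY1 by 5.21 (SE 0.11) and PGM2 by 5.08 (SE 0.13) (adjusted p = 1.3e-12, and adjusted p = 0.30 with an estimated correlation).

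All 53 ribosome biogenesis genes fell with the treatment, with a median of -2.41 (adjusted p = 4.4e-21, and adjusted p = 0.30 with an estimated correlation), among them SSF1 at -4.45 (SE 0.14) and NOG2 at -4.21 (SE 0.13). Of the ribosomal protein genes 129 of 137 fell (adjusted p = 5.1e-11, and adjusted p = 0.55 with an estimated correlation). Of the ATP synthase genes 13 of 14 fell, ATP3 by 1.09 (SE 0.07) (adjusted p = 0.00024, and adjusted p = 0.52 with an estimated correlation). TCA cycle genes rose in 14 of 15 cases, CIT1 by 1.42 (SE 0.07) (adjusted p = 0.00062, and adjusted p = 0.55 with an estimated correlation). The iron regulon rose in 17 of 25 cases, FET3 by 1.20 (SE 0.07) and FIT3 by 2.02 (SE 0.14), with FRE1 and FTR1 lower by 0.57 (SE 0.07) and 0.24 (SE 0.08) (adjusted p = 0.00075, and adjusted p = 0.24 with an estimated correlation). PDR5 rose by 1.10 (SE 0.10), and CIT2 was at -0.32 (SE 0.23, adjusted p = 0.23).

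In treated cells without SNF1, HXT4 fell from 1605 ± 269 to 46.5 ± 7.45 RPKM, HXT2 by 4.84 (SE 0.29), HXK1 by 3.36 (SE 0.15) and SUC2 from 211 ± 69.9 to 40.4 ± 3.32 RPKM. The sugar genes fell in 11 of 15 cases, MTH1 by 2.91 (SE 0.09) (adjusted p = 0.00028, and adjusted p = 0.40 with an estimated correlation). Of the stress genes 25 of 30 fell, GSY1 by 4.35 (SE 0.11), with SSA3 higher by 0.57 (SE 0.17) (adjusted p = 3.6e-08, and adjusted p = 0.41 with an estimated correlation). TCA cycle genes fell in 14 of 15 cases, MDH1 by 1.18 (SE 0.08) (adjusted p = 7.0e-06, and adjusted p = 0.41 with an estimated correlation). Ribosome biogenesis genes rose in 53 of 53 cases, with a median of 1.41 (adjusted p = 1.8e-22, and adjusted p = 0.41 with an estimated correlation), NOG2 by 3.19 (SE 0.13). Mitochondrial ribosome genes rose in 67 of 76 cases, MRPL3 by 1.01 (SE 0.06), with MEF2 lower by 0.28 (SE 0.09) and RSM10 by 0.25 (SE 0.05), though RSM10 was at 0.02 without rescaling (adjusted p = 3.2e-14, and adjusted p = 0.41 with an estimated correlation). PDR5 rose by 1.43 (SE 0.10). The mating type a genes again fell in 7 of 7 cases (median -4.44). The comparison called 4131 genes, 1992 higher and 2139 lower, or 3308 and 1147 without rescaling, with a shift of 0.26 in the median.

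The change in cells without SNF1 differed between treated and untreated cells for 3132 genes, 1563 higher and 1569 lower (2065 and 1117 without rescaling, with a shift of 0.13). HXK1 differed by -2.49 (SE 0.21), SUC2 by -2.27 (SE 0.27) and 11 of 15 sugar genes (median -1.74, adjusted p = 5.1e-06, and adjusted p = 0.26 with an estimated correlation). It also differed for 26 of 30 stress genes (median -2.11, adjusted p = 1.4e-13, and adjusted p = 0.34 with an estimated correlation) and 53 of 53 ribosome biogenesis genes (median 1.53, adjusted p = 2.9e-27, and adjusted p = 0.34 with an estimated correlation).

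MIG1 (YGL035C, chromosome VII, 431548 to 433062) encodes the repressor that Snf1 inactivates, and the MIG1 set deleted it in treated cells without SNF1, where MIG1 mRNA went from 22.9 ± 0.837 to 0.126 ± 0.112 RPKM (SD, n = 3 each). The deletion raised sugar uptake genes, HXT4 from 28.8 ± 6.37 to 1086 ± 160 RPKM, HXK1 from 179.9 ± 43.5 to 1196 ± 88.8 RPKM, SUC2 from 25.6 ± 1.11 to 65.0 ± 10.2 RPKM, HXT3 by 1.80 (SE 0.07) and HXT2 by 2.11 (SE 0.20). Of the 7 hexose transporters 6 rose (median 1.91, adjusted p = 1.1e-05, and adjusted p = 0.16 with an estimated correlation). Of the 17 sugar genes 10 rose, MTH1 by 2.58 (SE 0.08) and REG2 by 2.21 (SE 0.11), with the near-identical HXT15 and HXT16 each lower by 0.31 (SE 0.08) (adjusted p = 2.0e-05, and adjusted p = 0.34 with an estimated correlation). Of the stress genes 24 of 30 rose, DDR2 by 1.87 (SE 0.09) (adjusted p = 7.9e-12, and adjusted p = 0.27 with an estimated correlation). Mitochondrial ribosome genes rose in 39 of 76 cases, 56 adjusted over the list alone (median 0.22, adjusted p = 2.3e-12, and adjusted p = 0.36 with an estimated correlation). Complex III genes rose in 8 of 9 cases, QCR8 by 0.62 (SE 0.07) (adjusted p = 5.4e-05, and adjusted p = 0.16 with an estimated correlation).

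Against these, ribosome biogenesis genes fell in 32 of 53 cases (median -0.28, adjusted p = 1.1e-12, and adjusted p = 0.36 with an estimated correlation). Drug resistance genes fell in 8 of 11 cases, PDR15 by 1.45 (SE 0.16) and PDR5 by 1.03 (SE 0.18) (adjusted p = 3.5e-05, and adjusted p = 0.36 with an estimated correlation). Of the TCA cycle genes 9 of 15 rose, SDH3 by 0.67 (SE 0.06), while ACO1, IDH1 and IDH2 fell by 0.78 (SE 0.08), 0.64 (SE 0.08) and 0.64 (SE 0.06) (adjusted p = 0.024, and adjusted p = 0.36 with an estimated correlation). The comparison called 2111 of 6847 genes, 1083 higher and 1028 lower (553 and 1229 without rescaling), and 1355 and 1285 without libraries 1 and 2 of the strain that keeps MIG1. Library 3 stood apart in both groups, with a chi-square per degree of freedom of 35.5 and 37.2 (10.7 between libraries 1 and 2) in the strain with MIG1 and 40.9 and 74.5 (18.2) without it.

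**Figure D2:**
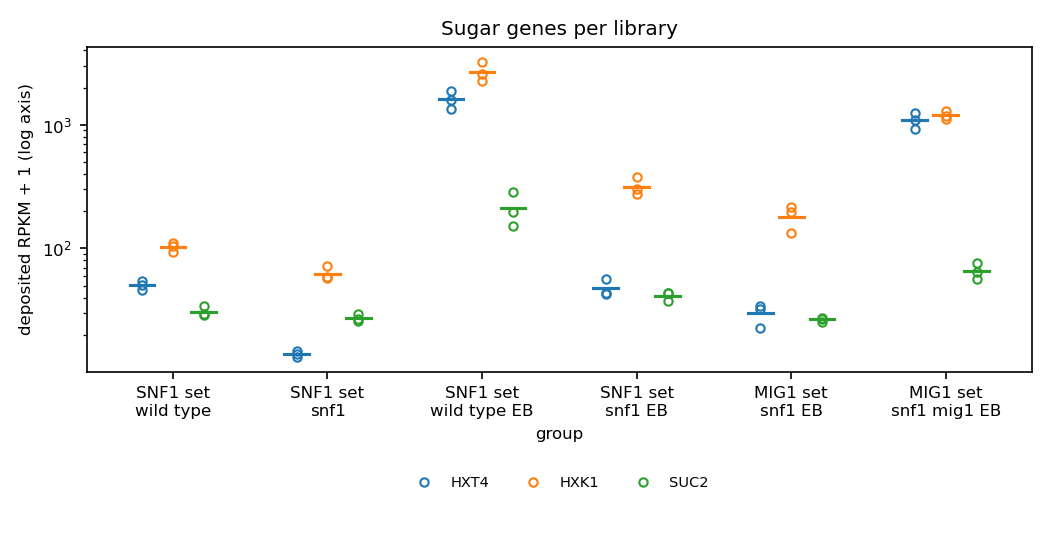
Level of HXT4, HXK1 and SUC2 in each library of the SNF1 and MIG1 sets (vertical axis, deposited RPKM + 1, log scale; horizontal axis, the group; EB, ethidium bromide); circles are libraries and bars are means, 3 libraries per group. HXT4 averages 1605 RPKM in treated wild type and 46.5 RPKM in treated cells without SNF1, and 28.8 and 1086 RPKM in treated snf1 cells with and without MIG1.

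INH1 (YDL181W, chromosome IV, 135179 to 135436) encodes the inhibitor that stops the ATP synthase from running in reverse. The INH1 set raised its mRNA in rho0 from the copper-driven CUP1 promoter, to ask what more of the inhibitor does in cells without mitochondrial DNA. INH1 was at 77.6 ± 2.17 RPKM in rho0, 295 ± 7.75 in rho0 with the construct, 1931 ± 22.2 with the construct and copper and 230.2 ± 6.91 in wild type (SD, n = 3 each). OLI1 was listed at 0 in all 9 rho0 libraries. No group received copper without the construct, so that the effects of copper and of the inhibitor are mixed in the comparisons with copper.

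The construct with copper changed 5061 of 6733 genes against rho0, 2507 higher and 2554 lower. Mitochondrial genes rose, with 75 of 76 for the mitochondrial ribosome (median 0.71; limma's camera test, adjusted p = 2.6e-21), among them MEF1 at 0.87 (SE 0.02) and TUF1 at 0.80 (SE 0.02). All 14 ATP synthase genes rose, ATP15 by 0.63 (SE 0.03) (adjusted p = 1.5e-05), and all 15 of complex II and the TCA cycle, SDH2 by 1.37 (SE 0.03) and CIT1 by 1.10 (SE 0.03) (adjusted p = 7.3e-08). Assembly factors rose in 26 of 30 cases, COX17 from 372 ± 6.57 to 1035 ± 21.5 RPKM and CBP4 by 1.55 (SE 0.04), with HEM1 lower by 0.13 (SE 0.03) (adjusted p = 3.7e-08). Import genes rose in 24 of 32 cases, MDJ1 by 1.42 (SE 0.02), with TOM70 and TIM21 lower by 0.24 (SE 0.02) and 0.21 (SE 0.04) (adjusted p = 6.1e-06).

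In the same comparison genes of gluconeogenesis and acetate use rose in 16 of 17 cases, MLS1 by 2.38 (SE 0.12) and IDP2 by 2.07 (SE 0.06) (adjusted p = 3.2e-06). The Adr1-dependent genes, for peroxisomes and ethanol use, rose in 11 of 13 cases, GUT2 by 1.25 (SE 0.03) (adjusted p = 0.00069), and sugar genes in 12 of 15, HXK1 by 1.87 (SE 0.04) (adjusted p = 0.0029, and adjusted p = 0.16 with an estimated correlation). Hexose transporters rose in 6 of 7 cases, HXT3 by 1.80 (SE 0.03), with HXT2 lower by 1.94 (SE 0.07) (adjusted p = 0.046, and adjusted p = 0.34 with an estimated correlation). Stress genes rose in 29 of 30 cases, HSP26 from 52.5 ± 5.36 to 1267 ± 39.6 RPKM and DDR2 by 3.72 (SE 0.31) (adjusted p = 2.9e-12, and adjusted p = 0.099 with an estimated correlation). All 11 drug resistance genes rose, ICT1 by 2.15 (SE 0.03) and PDR5 by 1.23 (SE 0.02) (adjusted p = 3.2e-06), as did 18 of 25 iron genes, SIT1 by 1.99 (SE 0.06), with VHT1 lower by 0.28 (SE 0.05) (adjusted p = 3.7e-05).

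Copper-responsive genes rose in 5 of 8 cases, CUP1-1 from 12.3 ± 3.88 to 149 ± 1.18 RPKM, CRS5 by 2.50 (SE 0.06) and SOD1 by 0.75 (SE 0.02) (adjusted p = 0.025, and adjusted p = 0.099 with an estimated correlation). Zinc-responsive genes rose in 6 of 9 cases, ZRT1 by 2.48 (SE 0.07), with ADH4 lower by 0.34 (SE 0.04) (adjusted p = 0.034, and adjusted p = 0.099 with an estimated correlation). Of the ribosomal protein genes 135 of 137 fell, RPL9A by 2.17 (SE 0.03), and RPL15B rose by 0.33 (SE 0.05) (adjusted p = 8.2e-35). Ribosome biogenesis genes fell in 52 of 53 cases, RRP5 by 1.37 (SE 0.02) (adjusted p = 3.0e-14), and amino acid genes in 29 of 31, LEU9 by 1.72 (SE 0.03), while CPA1 and LYS1 rose by 0.77 (SE 0.02) and 0.25 (SE 0.04) (adjusted p = 1.9e-09). Mating type a genes fell in 6 of 7 cases, BAR1 by 2.13 (SE 0.04) (adjusted p = 0.0098, and adjusted p = 0.11 with an estimated correlation).

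Without copper the construct alone, with INH1 higher by 1.91 (SE 0.03), changed 1188 genes, 657 higher and 531 lower, of which 12 rose and 2 fell at least 2-fold. Of the stress genes 28 of 30 rose by a median of 0.39, HSP26 by 1.06 (SE 0.06) (adjusted p = 3.3e-25). Zinc-responsive genes rose in 6 of 9 cases, ZRT1 by 2.57 (SE 0.07) and ZRT2 by 0.81 (SE 0.05) (adjusted p = 8.9e-08). TCA cycle genes rose in 10 of 15 cases, CIT1 by 0.26 (SE 0.03) (adjusted p = 1.0e-09), and iron genes in 10 of 25, FET3 by 0.35 (SE 0.04) (adjusted p = 1.6e-07). The mitochondrial ribosome rose in 19 of 76 cases, 31 adjusted over the list alone, with a median of 0.07 and RSM22 lower by 0.11 (SE 0.03) (adjusted p = 6.5e-10). HO fell from 60.2 ± 1.89 to 4.21 ± 0.296 RPKM, and CUP1-1 was at -0.58 (SE 0.21, adjusted p = 0.077). Without library 2 of the construct the count was 738. Copper added to the same construct changed 4818 genes, 2342 higher and 2476 lower, with CUP1-1 higher by 4.04 (SE 0.21). It raised 75 of 76 mitochondrial ribosome genes by a median of 0.64 (adjusted p = 1.0e-22).

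Against wild type, the rho0 strain of this set had 4739 genes called, 2343 higher and 2396 lower, or 2981 and 1774 without rescaling, with a shift of 0.11 in the median. PDR5 rose from 117 ± 1.86 to 1189 ± 5.35 RPKM, HSP12 by 3.62 (SE 0.03) and 75 of 76 mitochondrial ribosome genes (median 0.66), with MEF2 lower by 1.29 (SE 0.09). All 14 ATP synthase genes (median -0.76), 136 of 137 ribosomal protein genes and 53 of 53 ribosome biogenesis genes fell, and INH1 fell by 1.67 (SE 0.03). Mating type a genes rose in 7 of 7 cases, and wild type here had MFA1 at 3.41 ± 2.09 RPKM against 668 ± 6.37 in rho0.

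The OXPHOS, PUF3, Puf3-15A, INH1 and SNF1 sets each compared cells without mitochondrial DNA with wild type. In these 5 comparisons 1158 of 6616 genes were called in the same direction, 689 higher and 469 lower, where independent calls would share 23.7. The mitochondrial ribosome gave 56 of its 76 genes to the shared rise and 1 to the shared fall, assembly factors 21 of 30 to the rise, glycolysis 10 of 16 and drug resistance 5 of 11. The ATP synthase gave 12 of 14 to the shared fall, ribosomal proteins 42 of 137 and the phosphate regulon 7 of 14. A further 972 genes were called in opposite directions in at least 1 pair of these comparisons.

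The footprint set measured ribosome-protected fragments in wild type, the puf3 deletion, rho0 and rho0 without PUF3, with cycloheximide added for 2 min, to ask whether translation follows the mRNA. PUF3 footprints were at 34.7 ± 0.487 RPKM in wild type, 42.4 ± 1.20 in rho0, 0.205 ± 0.0892 in the puf3 deletion and 0.0818 ± 0.116 in rho0 without PUF3 (SD, n = 2 each). In rho0 the mitochondrial ribosome genes had more footprints in 62 of 76 cases, 69 adjusted over the list alone, with a median of 0.66 and IMG2 at 1.29 (SE 0.11), while MEF2 fell by 1.73 (SE 0.32) (limma's camera test, adjusted p = 1.3e-21, and adjusted p = 0.15 with an estimated correlation). Footprints on ATP synthase genes fell in 7 of 14 cases, ATP2 by 1.15 (SE 0.09) (adjusted p = 3.3e-05, and adjusted p = 0.23 with an estimated correlation). On ribosomal protein genes they fell in 84 of 137 cases, RPL8B by 0.81 (SE 0.07) (adjusted p = 3.7e-21, and adjusted p = 0.37 with an estimated correlation). Stress genes rose in 21 of 30 cases, DDR2 by 3.10 (SE 0.37) (adjusted p = 2.4e-10, and adjusted p = 0.42 with an estimated correlation).

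The largest rises in rho0 were in mating genes, 7 of 7 of the mating type a list (median 4.66, adjusted p = 1.0e-09, and adjusted p = 0.076 with an estimated correlation). Wild type of this set had MFA1 at 8.13 ± 7.23 RPKM, against 545 ± 26.8 in rho0, 495 ± 52.3 in the puf3 deletion and 463 ± 10.7 in rho0 without PUF3. The comparison called 1568 of 6348 genes, 799 higher and 769 lower, or 1082 and 548 without rescaling, with a shift of 0.12 in the median. It called 939 without wild-type library 1 and 908 with only the groups compared in the fit.

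Deleting PUF3 in wild type changed footprints of 85 genes, 63 higher and 22 lower. Mating type a genes rose in 6 of 7 cases (adjusted p = 1.6e-23). Of the import genes 4 of 32 rose, 13 adjusted over the list alone, TIM10 by 0.94 (SE 0.09) and HSP10 by 0.79 (SE 0.11) (adjusted p = 6.0e-11, and adjusted p = 0.11 with an estimated correlation). Of the mitochondrial ribosome genes 6 of 76 rose, MRPL50 by 0.92 (SE 0.13) (median 0.19, adjusted p = 5.2e-08, and adjusted p = 0.29 with an estimated correlation). The count was 51 without wild-type library 2, 37 and 38 without either puf3 library, 40 with only the groups compared and 202 with voom on recovered reads.

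In rho0 the same deletion lowered footprints of the mitochondrial ribosome in 29 of 76 cases, 53 adjusted over the list alone, with a median of -0.51, RML2 from 109 ± 1.96 to 54.6 ± 2.35 RPKM and MRPL4 by 1.11 (SE 0.12) (adjusted p = 1.0e-26, and adjusted p = 0.11 with an estimated correlation). Retrograde targets rose in 4 of 8 cases, CIT2 by 0.80 (SE 0.11) and DLD3 by 0.49 (SE 0.07) (adjusted p = 0.00011, and adjusted p = 0.11 with an estimated correlation). Drug resistance genes rose in 3 of 10 cases, RSB1 by 1.24 (SE 0.21) and PDR5 by 0.56 (SE 0.10) (adjusted p = 3.0e-05, and adjusted p = 0.11 with an estimated correlation). Of the 285 genes called, 88 were higher and 197 lower, or 155 and 74 without rescaling, with a shift of 0.16. The count fell to 50 without rho0 library 1, to 1 without either library of rho0 without PUF3 and to 1 with only the groups compared, and it was 567 with voom on recovered reads.

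Translational efficiency, the footprint change beyond the mRNA change, joined these libraries with mRNA of the same genotypes in the PUF3 set, from other cultures. For rho0 against wild type it differed for 484 of 6268 genes, 238 higher and 246 lower (359 and 158 without rescaling, with a shift of 0.13). High values were in mating genes, STE2 at 4.93 (SE 0.21), FUS3 at 3.34 (SE 0.23) and 6 of 7 of the mating type a list (adjusted p = 2.8e-16), whose wild-type values were low in footprints and only partly low in mRNA. OLI1 at 4.25 (SE 0.48) had footprints at 0 in both groups and owes its value to the lost mRNA, and 470 genes differed once mitochondrially encoded genes were left out. RME1 at 3.20 (SE 0.19) and HO at 4.00 (SE 0.29) rose with the mating genes, and IME4, made in diploids, fell by 2.92 (SE 0.27). Phosphate genes rose in 7 of 14 cases, VTC3 by 1.08 (SE 0.20) and VTC1 by 0.72 (SE 0.12) (adjusted p = 2.0e-08). Zinc-responsive genes fell in 6 of 9, ZRT2 by 1.35 (SE 0.17) (adjusted p = 3.5e-06, and adjusted p = 0.29 with an estimated correlation). PDR5 fell by 0.52 (SE 0.10) and PDR15 rose by 1.03 (SE 0.20). The count was 819, 260 and 264 without mRNA libraries 1, 2 and 3 of wild type, 848, 238 and 246 without those of rho0 and 287 without footprint wild-type library 2. It was 122 with only these genotypes in the fit, 96 with voom and 204 with a separate spread for each assay.

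For the puf3 deletion, efficiency differed for 37 genes in wild type, 27 higher and 10 lower, which became 18 once mating-type and haploid genes were left out, 23 with voom and 175 without mRNA wild-type library 1, and CSS1 fell by 3.27 (SE 0.29). In rho0 it differed for 512, 200 higher and 312 lower (336 and 92 without rescaling, with a shift of 0.11). The count was 851, 201 and 186 without mRNA libraries 1, 2 and 3 of rho0, 288, 207 and 254 without those of rho0 lacking PUF3, and 313 and 207 without footprint libraries 1 and 2 of the latter. It was 120 with voom and 147 with a separate spread for each assay. TCA cycle genes fell in 4 of 15 cases, ACO1 by 0.59 (SE 0.12) (adjusted p = 1.1e-06, and adjusted p = 0.24 with an estimated correlation). ATP synthase genes fell in 5 of 14, ATP1 by 0.61 (SE 0.11) (adjusted p = 8.8e-06, and adjusted p = 0.24 with an estimated correlation). Stress genes fell in 6 of 30, SSA3 by 1.12 (SE 0.20) (adjusted p = 9.4e-06, and adjusted p = 0.56 with an estimated correlation). NCE103 fell by 2.75 (SE 0.48) and PDR5 by 0.61 (SE 0.10).

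**Figure D3:**
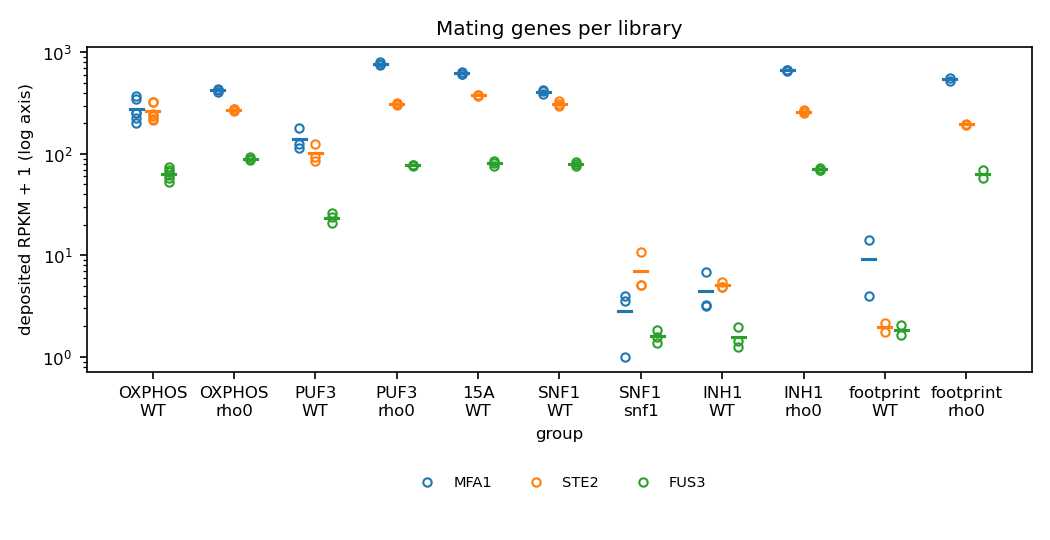
Level of the mating genes MFA1, STE2 and FUS3 in each library of 11 groups (vertical axis, deposited RPKM + 1, log scale; horizontal axis, the set and group, with WT for wild type and 15A for the Puf3-15A set); circles are libraries and bars are means. MFA1 averages 1.85 RPKM in the snf1 deletion, 3.41 in wild type of the INH1 set and 8.13 in wild type of the footprint set, against 274 in wild type of the OXPHOS set and 138 in wild type of the PUF3 set.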

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

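The tests of explanations and of other splits below were chosen only after the results were seen. The effect of a change differed between backgrounds, by limma's test of the interaction, for 507 genes for the PUF3 deletion in the atp7 deletion against wild type, among them ZPS1 (2.78), IMD2 (2.15), ADH4 (1.86), MFA1 (-2.42), FUS3 (-2.09) and STE2 (-2.07, all log2). For the PUF3 deletion in rho0 against wild type it differed for 2514 genes, with NCE103 at 3.48, HSP12 at 3.42, IMD2 at 2.75, MFA1 at -2.84, STE2 at -2.33 and AGA2 at -2.23. For puf3-15A it differed for 1272 genes, with CIT1 at 1.23, PIR3 at 1.22, ECM13 at 1.20, SPL2 at -1.47, PHO12 at -1.09 and PHM6 at -1.06. For the SNF1 deletion it differed for 3132 genes, with NOG2 at 3.17, SLM6 at 3.03, BSC1 at 3.03, HXT6 at -4.81, DDR2 at -4.70 and RCK1 at -4.52. Among the 6 wild-type libraries of the OXPHOS set, 1 library stood apart from the others by Dixon's criterion for 5 of 41 genes: library 1 for GIT1 (69.6 RPKM, median 40.2), HPF1 (294.6, median 162.6), SRD1 (17.3, median 22.0) and SUE1 (11.1, median 5.83), and library 3 for HMX1 (36.5, median 39.9). Chance marks about 1 in 20 such groups.

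Genes of mating type a cells and of haploid cells were low in 6 groups: both groups of the SNF1 set without SNF1, both of the MIG1 set, wild type of the INH1 set and wild type of the footprint set, and they were partly low in wild type of the PUF3 set. Loss of SNF1 is argued against as the cause in every such group, since in the INH1 set wild type, which has SNF1, the median a-specific gene was at 1.56% of its level in rho0. In the groups without SNF1, at up to 4.93% of wild type, it cannot be told apart from another cause, because each of them is low and none has SNF1 restored. Cells of mating type alpha are argued against too, because these would keep haploid-specific genes, whose median was at most 19.8% of the partner group in the SNF1, INH1 and footprint sets, with single genes at 0.40% to 131%; this test replaced an earlier one that decided nothing, in which the highest alpha-specific gene, SAG1, reached 24.1 RPKM. Cells that hold both mating types would have a-specific and haploid-specific genes low together, as at this 19.8%, so diploid cells or a mixed mating type may be present in these groups, which remains a hypothesis. The design names no ploidy, and a strain that differs from its label stays open, so that changes between these groups and their partners cannot be assigned to SNF1, rho0 or PUF3 alone.

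Wild-type libraries 4 to 6 of the OXPHOS set differed from libraries 1 to 3 in 2909 genes. Sequencing depth is argued against, since 55.2% of the genes at or above 100 RPKM were called and the mean depths were 11927837 and 12062087 reads, and so is the scaling, since 99.3% of the calls were met again with median-ratio size factors. All 53 ribosome biogenesis genes were higher and 25 of 30 stress genes lower in libraries 4 to 6, as growth state at harvest could give, a result seen before this test was written. In sample order, libraries 1 to 3 sit with the deletions and 4 to 6 with rho0. A second day of culture stays open, and no biological explanation was tested.

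Glucose-repressed sugar genes rose by a median of 2.37 (log2) in wild type treated with ethidium bromide. Established loss of mitochondrial DNA is argued against, since their highest median over the drug-free rho0 strains of the other 4 sets was 0.38. The bound was reworded once this was seen. Exhaustion of glucose should strongly raise FBP1, PCK1, ICL1, MLS1, JEN1 and ADH2, whose median ratio of 1.76 argues against it, though a partial fall could remain. Recent loss and the drug were not told apart, as no treated group kept its mitochondrial DNA.

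Other splits of the same libraries were fitted with limma. In the OXPHOS set, rho0 gave 3296 genes against 2296 in the highest other split (1 of 84 splits as large). The atp7 deletion gave 3058 against 3334 (2 of 84), and cor1 and cox9 420 against 2914 and 448 against 2966 (3 of 84 each). Chance can be excluded for any of these only if the 6 wild-type libraries are taken as alike. They are not: the highest other split set libraries 4 to 6 apart each time, several times the real count for cor1 and cox9 (589 and 565 against libraries 1 to 3 alone), which points to structure among them. For the interactions the splits also move libraries between genotypes, whose main effects enter the counts, so that they decide little: PUF3 in rho0 gave 2514 against 2040 (1 of 100 splits as large), SNF1 3132 against 1425 (1 of 100), puf3-15A 1272 against 4493 (3 of 100, the highest following whole groups) and PUF3 in the atp7 deletion 507 against 3441 (5 of 100).

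With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real count and the highest other were 1066 and 605 for PUF3 in wild type, 152 and 0 in the atp7 deletion and 2077 and 3 in rho0. In the same set they were 3717 and 0 for the atp7 deletion and 2654 and 420 for rho0 against wild type. They were 935 and 0 for puf3-15A in wild type, 1220 and 0 in rho0, 3710 and 0 for rho0 of that set, 1975 and 0 for SNF1 in untreated cells, 4131 and 0 in treated cells, 4880 and 0 for the treatment and 2111 and 0 for MIG1, where the others include the splits that part all 3 pairs. In the INH1 set they were 4739 and 0 for rho0, 5061 and 1 for the construct with copper, 4818 and 0 for copper and 1188 and 1 for the construct alone.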

How the results depend on the processing

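The later settings were chosen after seeing the data. For counts of called genes, 298 of the runs with another setting stayed within 1.5 times the main value and 22 did not, and for named genes 10945 kept direction and side of the threshold, 222 lost their call and 117 gained one. A stable count need not hold the same genes: such MIG1 runs, leave-outs included, kept 1383 to 2109 of 2111 calls. As libraries were left out in turn, 7660 kept both, 461 lost their call and 80 gained one. Only 2 values reversed. RSM10 in treated cells without SNF1 was at 0.0198 without rescaling, which shifts all genes of that comparison up by a median of 0.26. The other was PUF3 mRNA itself in the interaction in rho0, at 0.0897 with voom against -0.62, both groups without PUF3 being near 0. With only the compared groups in the fit, the spread rests on fewer libraries: cor1 gave 132, cox9 235, PUF3 in wild type 174, in the atp7 deletion 549 and in rho0 1361, rho0 of the PUF3 set 1270, puf3-15A in wild type 496, rho0 footprints 908, PUF3 footprints in wild type 40 and in rho0 1, and efficiency in rho0 122. Against wild-type libraries 4 to 6 alone, cor1 gave 2840 and cox9 2871, with no cause tested beyond the difference between the trios. Voom gave 202 and 567 for PUF3 footprints in wild type and rho0, and 96, 23 and 120 for efficiency in rho0, the PUF3 deletion and the PUF3 deletion in rho0, and a separate spread for each assay gave 204 and 147 for efficiency in rho0 and for PUF3 in rho0; the cause was not tested. Without mating-type and haploid genes, and so with fewer genes tested, efficiency for the PUF3 deletion gave 18. With the correlation between genes estimated from the data, 113 list tests passed against 443 of 839 at the preset value. The shared responses stayed between 942 and 1198 genes (cells without mitochondrial DNA) and between 102 and 204 (OXPHOS mutants).

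Leaving out 1 library at a time gave 259 to 567 for cor1, 217 to 628 for cox9, 404 to 2402 for PUF3 in wild type, 341 to 1787 for its interaction in the atp7 deletion, 525 to 1100 for puf3-15A in wild type, 770 to 1339 for its interaction, 1285 to 1967 for MIG1, 738 to 948 for the INH1 construct, 939 to 1427 for rho0 footprints, 37 to 64 and 1 to 212 for PUF3 footprints in wild type and rho0, and 238 to 848, 33 to 175 and 186 to 851 for efficiency in rho0, for PUF3 and for PUF3 in rho0. For the other comparisons each of these counts stayed within 1.5 times. A lone footprint library left in a group was assumed to vary like those of the other groups. The replicate number as a block moved no count by over 1.5 times. The residuals of libraries with the same number were correlated by 0.129 to 0.433 for MIG1, where 3 of 3 libraries matched their own number best (block 2665 against 2111), and by 0.201 to 0.363 for rho0 in the PUF3 set, where 2 of 3 did (block 2705 against 2654). In the efficiency fit the latter libraries gave 0.269 to 0.407 (block 457 against 484), and rho0 of the INH1 set gave 0.022 to 0.052, with the lowest pair below 0 in the other mRNA comparisons. The planned DESeq2 test, its calls for the shared responses and the list of genes with a Puf3 motif with its variants were not run. In simulations 32% of 1.5-fold changes were recovered for rho0 footprints and 30% in efficiency, against 92% in OXPHOS mRNA. Footprints have fewer reads and libraries, and depth alone was not varied.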
